A study of Homo sapiens with 8 samples.

How the data were processed

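MCF-7 cells transfected with a pool of siRNAs against TET2 or with a non-targeting pool were profiled by Methyl-Midi Seq and by reduced representation hydroxymethylation profiling (RRHP), with 2 libraries per treatment and assay. Per the labels' protocols, Methyl-Midi Seq libraries were made from DNA digested with TaqαI and MspI, size-selected on a gel and bisulfite-converted. RRHP libraries were made from MspI fragments whose adapter junctions were kept only where a glucosylated 5hmC blocked a second digestion. The submitters' processing notes name Bismark, Bowtie, methylKit and DESeq2 without versions or roles, and which step each tool ran is not given in the sources used here. The notes name the build GRCh37, but the contig names and chromosome ends in the files are those of GRCh38, and 44.2% of the 5hmC rows matched a listed CpG at an offset of 0 bp and 0% at 1 or 2 bp to either side, so the files of both assays share one build. All coordinates are given as GRCh38, 1-based, as in the files.

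Per the file headers, each bisulfite file gives the coverage as a count of reads for each CpG cytosine and strand, and the percent of those reads read as C or as T. The deposited files list only cytosines with at least 10 reads. Methylated reads were recovered as coverage times percent, and every listed percent lay within 0.005 points of that of a whole number of reads. In the 2 deposited 5hmC tables, the counts are whole numbers of tags per CCGG end and strand, listed where at least 1 of the table's 2 columns had a tag, and each row carries promoter, exon, intron and CpG island entries with gene names. The deposited ratio column, per the file headers, is the first count column over the second, with 0.001 in place of a count of 0, and it was used only to learn this. No column of per-sample values was left unused. Gene names are those of the tables: of 23673 names, 20970 matched a current symbol and 1598 an older one in the reference list used for names only.

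Library depth is given with the results. Replicates were first compared: the correlation of methylation levels between any 2 bisulfite libraries was 0.975 to 0.978 and chi-square per cytosine was 1.153 to 1.212, with no pair close enough to be 1 library under another name. The log2 gene values of the 5hmC columns correlated at 0.9949 for columns 1 and 3, 0.9867 for columns 2 and 4, and 0.9779 to 0.9854 for the other pairs. The bisulfite columns were mapped by the sample titles. The 5hmC columns carry no sample name or replicate number and were placed by the sample descriptions, which name a table for siNT and another for siTET2. The library numbers and the deposited ratio argue for 1 library of each treatment in each table, and the files could not settle it. A second contrast, of the second against the first column of each table with the table as a block, was therefore added after the data were seen, with no treatment named.

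For 5mC, autosomal and X cytosines with at least 10 reads in all 4 libraries were used. Means were taken with equal weight and weighted by reads, both as fixed before the data were examined, and group means were compared by an exact two-sided permutation test. Tiles were non-overlapping windows of 1 kb with at least 3 cytosines and 30 summed reads per library, and promoters used the same minimums over the cytosines that the 5hmC tables' entries place in a promoter, including cytosines between 2 such entries at most 2000 bp apart. The design had planned promoters as a fixed distance around start sites, for which no annotation of this build was used. Methylated and unmethylated reads were tested with edgeR's quasi-likelihood test, with an intercept per library and a treatment term on the methylated reads. Single cytosines were tested by a quasi-binomial likelihood ratio, leaving out the 0.1% of highest coverage, at an adjusted p under 0.05 and a difference of at least 25 percentage points. For 5hmC, tags were summed per gene name, per 1-kb tile or kept per site and strand, filtered with filterByExpr and scaled with TMM, and tested with edgeR's quasi-likelihood test. A gene thus holds the sites that the tables assign to it, its coordinates are those of its first and last such site, and sites assigned to overlapping genes count in each. All p-values over many features were adjusted by Benjamini-Hochberg at 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, and with fry. Gene levels use genes with at least 20 sites and are relative to all tags of a column. Bins of 1 Mb with at least 100 sites with at least 3 times the median tags per site are called high-tag bins, which rests on the tags themselves and not on a copy-number assay. Intervals and p-values do not cover PCR duplicates, since no molecular identifiers are in the files.

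The named genes follow a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among those that passed with both siTET2 libraries on the same side of both siNT libraries, or the 5 smallest p where fewer than 5 passed, plus TET2, ESR1, TFF1, GREB1, PGR, XBP1, GATA3 and FOXA1, plus up to 4 members of each of 11 fixed lists, without pseudogenes. Not all list members so chosen are printed. The fixed lists were oestrogen receptor targets, luminal identity, basal and mesenchymal, blood cells, 5mC and 5hmC machinery, genes often hypermethylated in breast cancer, HOX genes, imprinted genes, cell cycle, housekeeping, and genes amplified in MCF-7.

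The tests of 5mC tiles, promoters and cytosines and of 5hmC genes and tiles were run on simulated data drawn from the real libraries with 200 changed features; the test of single 5hmC sites and the gene-list tests were not. For 1-kb 5mC tiles it recovered 19% of changes of 10 points and 71% of 20 points, for promoters 76.5% of 10 points, for single cytosines 6.0% of 30 points and 76.0% of 60 points, for 5hmC genes by the descriptions 70% of 2-fold changes and for 5hmC tiles 0% of 2-fold and 55% of 4-fold changes. Between second and first columns it recovered 84% of 2-fold and 97% of 4-fold changes in genes. Calls among the unchanged features were 0 and 1 for 5mC tiles, 4 for promoters at 10 points, and 0 and 1 for cytosines. Promoter changes of 20 points were recovered at 93.5% with 14 such calls, those of 40 points at 100% with 8. Such calls were 16 for genes by the descriptions, 0 and 6 for 5hmC tiles, and 14 and 23 for genes between columns. In these single runs more than 5% of these gene calls and of the promoter calls at 20 points were false. The cytosine data were drawn with read sampling alone, without variation between libraries. Their recovery and false calls thus describe an easier setting than the real libraries. Alternatives were a coverage minimum of 20, tiles of 500 bp and 5 kb, other tests (limma, binomial, Fisher, F reference, DESeq2), RLE and total-tag scaling, no filter, blocks, and leaving out each library. A coverage minimum of 5 could not be tried because the files list cytosines from 10 reads. Oestrogen response element and other motif tiles were not analysed here, since no genome sequence was used. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, arrow 21.0.0 and the package data.table (version 1.17.8), and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.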

Results

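The series measured cytosine methylation and hydroxymethylation in MCF-7, an oestrogen receptor-positive breast cancer cell line. Cells were transfected with a pool of siRNAs against TET2 (siTET2) or with a non-targeting pool (siNT). TET2 is an enzyme that oxidises 5-methylcytosine (5mC) to 5-hydroxymethylcytosine (5hmC), and the title of the series names its role at regulatory regions bound by the oestrogen receptor as the subject. Methyl-Midi Seq, a bisulfite method on DNA cut with 2 restriction enzymes, reported 5mC and 5hmC together as one percentage per cytosine. RRHP, a restriction method that keeps only MspI sites (CCGG) with a protected 5hmC at the junction, reported 5hmC as tags per site. Each assay was run on 2 siNT and 2 siTET2 libraries, 8 in all. Nothing in the labels said that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333.

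The bisulfite files listed 4004729 and 4150254 CpG cytosines for siNT replicates 1 and 2, and 4037087 and 3646062 for siTET2 replicates 1 and 2. Their summed coverage was 85280314, 90343607, 85240760 and 74154054 reads in that order, with a median of 16 or 17 reads per listed cytosine and a minimum of 10. The 5hmC tables held 4 count columns with 36991815, 9193075, 30375040 and 13046901 tags for columns 1 to 4. The sample descriptions tied the table with columns 1 and 2 to siNT and the table with columns 3 and 4 to siTET2. The numbering of the libraries would instead put 1 library of each treatment in each table, siNT before siTET2 if the columns follow it. The ratio that the authors deposited in each table set its first column against its second. The columns themselves carried no sample name. The 5hmC comparison between treatments follows the descriptions, its libraries are called by column number, and its table and its treatment cannot be told apart. Neither assay measured TET2 expression, so the knockdown itself could not be checked.

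At cytosines covered in all 4 bisulfite libraries, DNA methylation was at nearly the same level in each, genome-wide and in each part of the genome. At the promoter of TET2, where 73 cytosines were covered, the level was 7.5% and 7.6% in the siNT libraries and 7.8% and 7.7% in the siTET2 libraries. Over 2493981 cytosines covered by at least 10 reads in every library, the mean level was 60.57% ± 0.07 (SD, n = 2) with siNT and 60.44% ± 0.5 (SD, n = 2) with siTET2, a difference of -0.13 percentage points (exact permutation test, two-sided p = 1.0). Weighted by reads, the means were 57.37% ± 0.31 and 58.19% ± 1.35 (SD, n = 2 each), and the difference had the opposite sign, 0.82 points (exact permutation p = 0.667). CpG islands, the CpG-dense stretches at many promoters, had 27.09% with siNT and 27.02% with siTET2. Cytosines outside islands had 79.51% and 79.39%. Promoters had 22.53% and 22.43%, exons 78.96% and 78.94%, introns 79.88% and 79.79%, and intergenic cytosines 73.71% and 73.58%. None of these class differences exceeded the SD of the siTET2 libraries. Over all cytosines listed per library, a set that differs between libraries, the siTET2 libraries lay further apart. Their unweighted levels were 65.59% and 62.31%, against 64.37% and 64.46% with siNT.

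**Figure D1:**
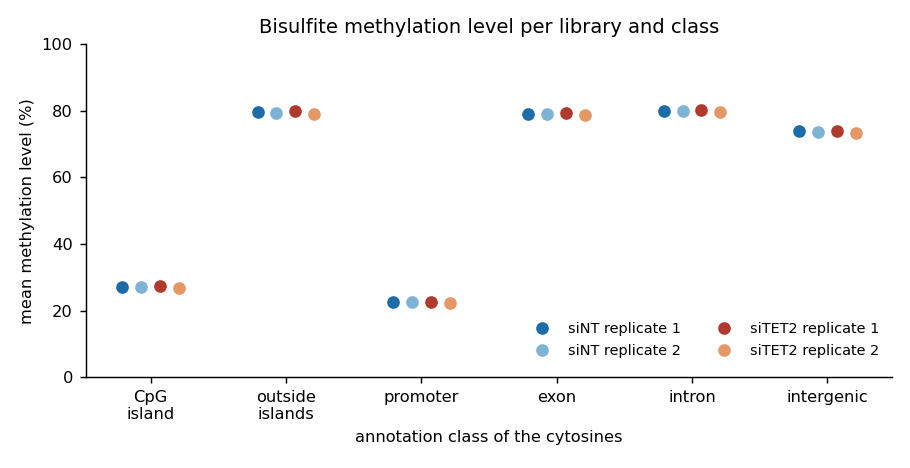
Mean bisulfite methylation level in percent (vertical axis) in 6 annotation classes of cytosines (horizontal axis), with 1 point per library: siNT replicates in blue, siTET2 replicates in red and orange. The 4 libraries lie together in every class, near 27% in CpG islands and near 79% outside them.

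No 1-kb tile passed as differentially methylated. Among 228347 tiles tested with edgeR's quasi-likelihood test on methylated and unmethylated reads, 0 had an adjusted p under 0.05, 9735 had an unadjusted p under 0.05, and limma also called 0, but 17 passed with the replicate number as a block and 691 without overdispersion. Among tiles with a gene entry, the 5 with the smallest p did not pass (adjusted p = 1 for each) and had higher values in both siTET2 libraries. An exonic tile of NHLH2, a neuronal transcription factor gene (chromosome 1, 115838000 to 115838999, GRCh38), had 37.7% and 40.6% with siNT and 46.3% and 48.5% with siTET2, from 5646 to 7036 reads per library. A promoter tile of CSF1, which encodes a macrophage growth factor, had 32.3% and 41.6% over the pooled reads of each group. The promoter tiles of CKB (a creatine kinase) and NMNAT2 (an NAD-synthesis enzyme) had 38.7% and 50.6%, and 43.9% and 56.4%. The fifth tile, at MIR3648-1 on chromosome 21, lies in ribosomal DNA, which is present in many copies, and had 57.7% and 69.7%. On simulated tiles the same test recovered 71% of changes of 20 percentage points and 19% of changes of 10 points, so most changes of the smaller size in single tiles were not recovered.

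The promoters of the oestrogen receptor gene and its partners had low methylation in all 4 libraries, and 0 of 14957 promoters passed (661 at an unadjusted p under 0.05, edgeR). ESR1, which encodes oestrogen receptor alpha, had 11.5% and 11.6% as the means of the 2 siNT and the 2 siTET2 libraries. FOXA1 and GATA3, luminal transcription factors that open sites for the receptor, had 12.6% and 12%, and 12% and 10.6%. XBP1 had 10.4% and 10.3%. The oestrogen-induced genes GREB1 and TFF1 had higher levels, 36.5% and 37.2%, and 35.7% and 31.5%. The PGR promoter had too few covered cytosines. The 5 promoters with the smallest p were EIF4E3, KREMEN1, MIR3648-1, NKX1-2 and WNK2, with 4.2 to 12.2 points more in siTET2 and an adjusted p of 1 each.

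Among the 11 gene lists fixed before the data were examined, 0 members of any list passed by promoter methylation, over all genes or adjusted over the list alone. Of 39 oestrogen receptor targets, 22 had a higher and 17 a lower value with siTET2 (median difference 0.05 points). The 21 luminal identity genes had a median difference of -0.1 points, the 22 basal and mesenchymal genes 0.09, the 12 blood cell genes -0.47 and the 25 genes of the 5mC and 5hmC machinery 0.19. For the 28 genes often hypermethylated in breast cancer the median was 0.23, for the 39 HOX genes 0.03, for the 21 imprinted genes 0.38, for the 22 cell cycle genes -0.01, for the 14 housekeeping genes 0.09 and for the 14 genes amplified in MCF-7 0.19.

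Single cytosines passed at 15 of 2488765 positions tested (quasi-binomial model, adjusted p under 0.05 and a difference of at least 25 points), 8 higher and 7 lower with siTET2. Lower values were found in an intron of PDE3A, a phosphodiesterase gene (-65.4 points, 10 to 16 reads per library), and near the start sites of PRIM1, a DNA primase subunit (-55.2), FOXA2, a forkhead factor of endoderm (-53.8), and TMEM108 (-40.8). Higher values were found near the start site of ITGA8, an integrin gene (53.0), and in introns of FHIT, a fragile-site gene (50.0), and MACROD2 (33.3). At all 15 both siTET2 libraries lay outside the range of the siNT libraries, which the call itself favours. The count depended on the reference distribution: 0 passed with an F reference with 2 residual degrees of freedom. That reference gave only 158 unadjusted p under 0.05. It could hardly call any cytosine at these depths, so its 0 does not test the 15 calls. The other splits of the same libraries gave 37 (replicate 1 of each group against replicate 2) and 6. Without siTET2 replicate 1 the count was 65.

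Most 5hmC tags lay outside CpG islands, 90.67% of them, but so did 84.5% of the listed sites. Averaged over the 4 columns, sites in CpG islands had 0.252 CPM per site (tag counts scaled to the total of their column) and sites outside had 0.451. Promoters had 0.268, introns 0.467, exons 0.549 and sites with no gene entry 0.408. In that order they held 8.85%, 43.27%, 7.61% and 40.27% of the tags and 13.9%, 38.9%, 5.8% and 41.4% of the sites. Compared with the bisulfite level of the siNT libraries at the same CpG, averaged over listed strands, sites at 0 to 10% had 0.198 CPM. Sites at 10 to 20% had 0.318, at 20 to 40% 0.449, at 40 to 60% 0.367 and at 60 to 80% 0.809. At 80 to 90% the value was 0.866 and at 90 to 100% 0.609. The mean did not rise steadily and was highest at sites that by this measure were mostly but not fully methylated. Within islands, 67747 site rows fell at 40 to 60% and 10604 at 0 to 10%, although island cytosines averaged 27.09% with siNT. Levels at these CCGG sites may thus differ from those of islands at large, which was not tested. The median tags per site in column 1 were 9 at 60 to 80%, 13 at 80 to 90% and 11 at 90 to 100%, and outside islands they were nearly flat at 12, 13 and 12. Outside islands, sites at 60 to 80% had 1.07, 0.873, 0.981 and 0.852 CPM in columns 1 to 4.

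**Figure D2:**
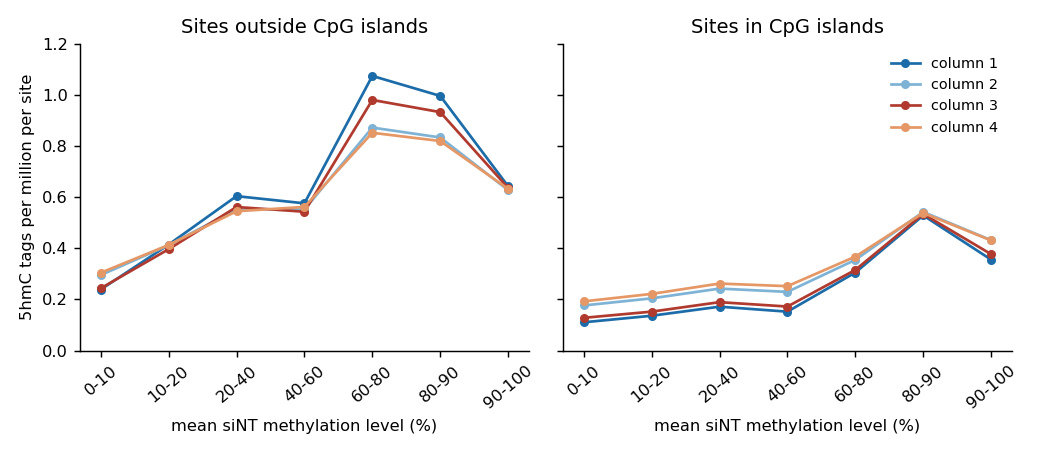
5hmC level in CPM per site (vertical axis) by the mean bisulfite methylation level of the siNT libraries in percent (horizontal axis), outside CpG islands (left) and within them (right), with 1 line per count column. Outside islands the 4 lines peak between 60 and 90% methylation, and within islands the values are lower in every class.

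The lists of oestrogen receptor targets and luminal identity genes had median 5hmC levels above that of all genes, with members at both ends. The median level of 37 oestrogen receptor targets with at least 20 sites was 0.465 CPM per site, the 76.8th percentile of 14189 protein-coding genes, whose median was 0.317. The 20 luminal identity genes stood at 0.471 (the 77.4th percentile). SPDEF, a luminal transcription factor gene, had 1.4, the trefoil peptide genes TFF3 and TFF1 had 1.28 and 1.18, GREB1 had 0.962, GATA3 0.674 and ESR1 0.616. FOXA1 had 0.376, XBP1 0.197 (the 17.1st percentile) and PGR, which encodes the progesterone receptor, 0.158. Low values were also found at AR (0.175) and ZNF703 (0.0722). TET2 had 0.344. The 17 cell cycle genes had a median of 0.219 (the 23.3rd percentile), the 10 housekeeping genes 0.271, the 26 genes often hypermethylated in breast cancer 0.271, the 19 basal and mesenchymal genes 0.28, the 14 imprinted genes 0.294, the 22 machinery genes 0.337, the 33 HOX genes 0.341 and the 7 blood cell genes 0.399. These are descriptions of levels over the 4 libraries, with no test between lists and no correction for copy number, and SPDEF, TFF3, AR and ZNF703 were picked for their level after it was seen, as were the genes of highest level named next.

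**Figure D3:**
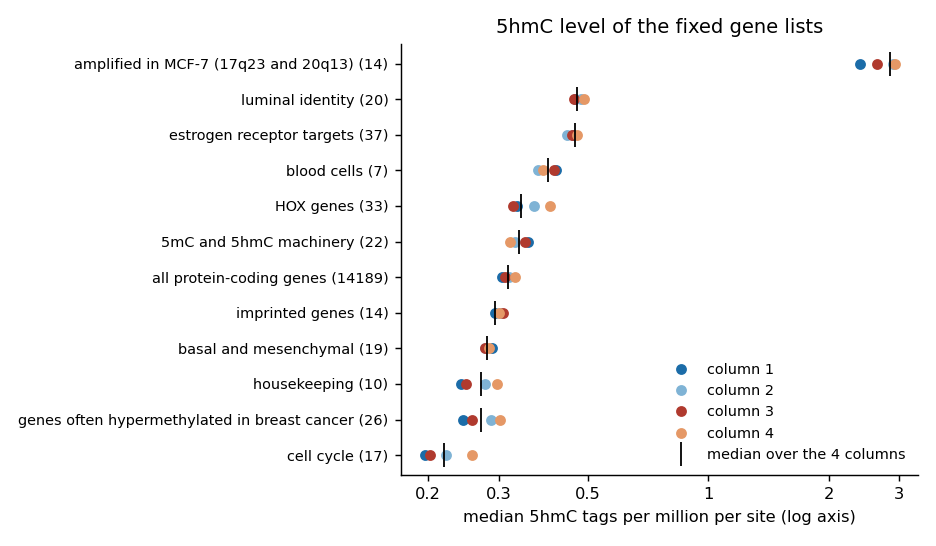
Median 5hmC level of each fixed gene list in CPM per site (horizontal log axis), with the number of genes in parentheses and 1 point per count column. The bar, labelled as the median over the 4 columns, is the median over genes of each gene's mean over the 4 columns. Oestrogen receptor targets and luminal identity genes lie above all protein-coding genes (0.317), and the list of genes amplified in MCF-7 lies highest.

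The genes amplified in this cell line had the highest median tag level of the fixed lists. The 14 genes of the 17q23 and 20q13 amplicons had a median of 2.85 CPM per site. The highest levels of all genes were 8.13 at TBX4, a T-box gene on chromosome 17, 7.76 at ZNF217, 7.5 at BMP7 and 7.41 at ZMYND8 on chromosome 20, and 5.06 at TBX2. Of 2875 bins of 1 Mb, 29 had at least 3 times the median tags per site, 12 of them on chromosomes 17 or 20. In the bin of chromosome 17 from 61000000 to 61999999 the tags were 15.5 times the genome median, and the bisulfite reads per cytosine were 8.53 times theirs. The highest bin was on chromosome 21 from 8000000, outside these amplicons, with 18.28 times the median tags and 6.75 times the reads. Bins on chromosome 12 from 37000000 and chromosome 5 from 60000000 had 11.68 and 10.27 times the tags but 0.95 and 1.25 times the reads, so a high tag level alone does not show a copy gain. Across bins the tag and read levels rose together (Spearman rho 0.649 across bins, which are not replicates), so a tag level is not a share of modified cytosines.

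**Figure D4:**
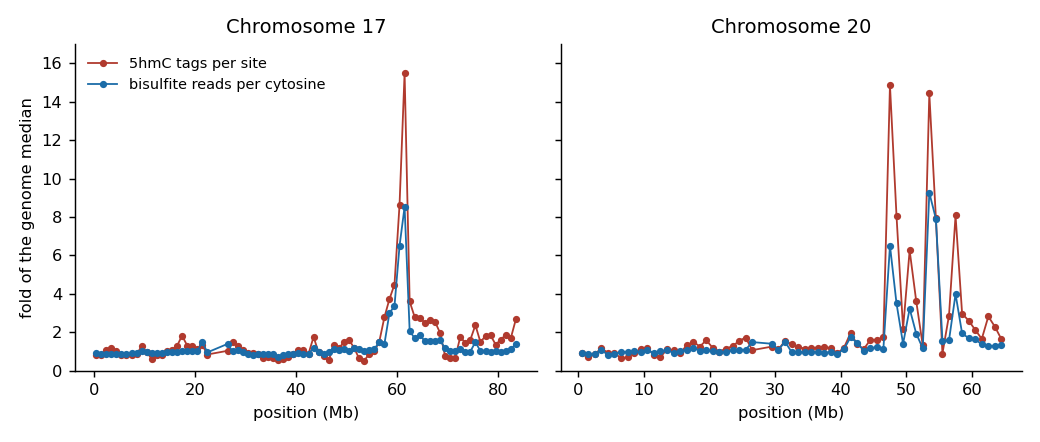
5hmC tags per site and bisulfite reads per cytosine, each as a fold of the genome median (vertical axis), in 1-Mb bins along chromosomes 17 and 20 (horizontal axis, Mb). Both measures peak in the same regions, and the tags reach 15.5 times the median near 61 Mb of chromosome 17.

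No gene passed for a difference in 5hmC between siTET2 and siNT with the libraries placed by the sample descriptions. The TET2 gene had 37.2 and 32.4 CPM in columns 1 and 2 and 34.1 and 28.2 in columns 3 and 4, a log2 change of -0.16 (SE 0.15). These CPM were scaled with TMM to the tags summed over the tested genes, not to the column total. ESR1 (chromosome 6, tagged sites from 151698020 to 152099866) had a log2 change of -0.21 (SE 0.16), TFF1 -0.14 (SE 0.18), GREB1 -0.02 (SE 0.21), PGR -0.03 (SE 0.19) and GATA3 -0.10 (SE 0.15). FOXA1 had 0.08 (SE 0.16) and XBP1 0.38 (SE 0.29). Of 22520 genes tested, 0 passed and 139 had an unadjusted p under 0.05 (edgeR), fewer than expected where no gene differs. Each group held a first and a second column, which differed in many genes, and that difference counted as spread within groups. With column position as a block, 1674 had an unadjusted p under 0.05 and 1 passed. The count of 0 is therefore not evidence of unchanged 5hmC. DESeq2 also called 0, and the adjusted p was 1 for each gene named here. Without column 1, 20 genes passed, all lower, and without columns 2, 3 and 4 in turn 2, 0 and 1 passed.

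**Figure D5:**
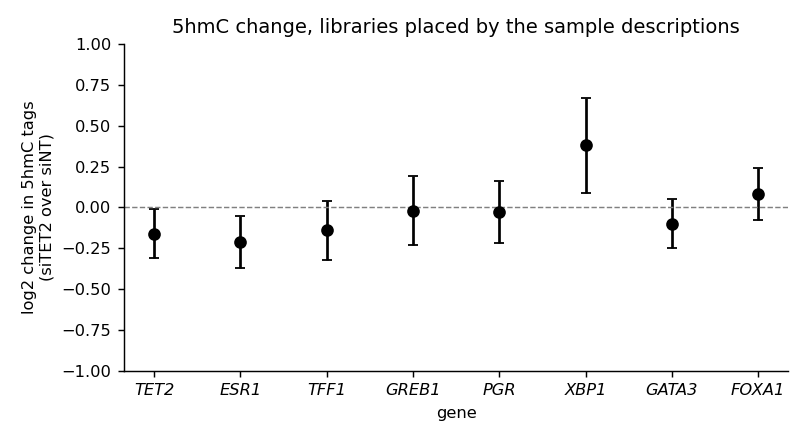
Log2 change in 5hmC tags, siTET2 over siNT with libraries placed by the sample descriptions (vertical axis), for the 8 genes named in advance (horizontal axis). Points are edgeR estimates from 2 libraries per group and bars are standard errors, and the values lie between -0.21 and 0.38.

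The 5 genes with the smallest p had few tags and did not pass. LINC00895, a non-coding RNA gene with 1 site, had 1 and 0 tags in columns 1 and 2 and 15 and 6 in columns 3 and 4. SNAR-B1 and SNAR-B2, near-identical small RNA genes that shared sites, had log2 changes of 1.41 (SE 0.31) and 1.35 (SE 0.33), MIR6773 2.30 (SE 0.59) and PSMD6-AS2 1.97 (SE 0.53). Among the fixed lists, 0 members of any list passed over all genes or adjusted over the list alone. Only the 22 cell cycle genes differed as a list, upwards (17 above and 5 below 0, median log2 0.19, camera adjusted p = 0.0266). That call was lost with an estimated correlation (adjusted p = 0.77), and also without column 1, without column 4 or with total-tag scaling. CCNA2 and RRM2 had the highest values of that list, 0.65 (SE 0.41) and 0.52 (SE 0.33), and CCNB2 the lowest, -0.18 (SE 0.21).

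In the other lists camera gave an adjusted p of at least 0.42. The 39 oestrogen receptor targets had a median log2 change of 0, with AREG at 0.58 (SE 0.40) and RAPGEFL1 at -0.23 (SE 0.15). The 20 luminal identity genes had a median of -0.07, with ZNF703 at 0.35 (SE 0.27) and GRHL2 at -0.22 (SE 0.14). Of the 25 machinery genes 20 lay below 0 (median -0.04), with MBD4 at 0.64 (SE 0.31) and APOBEC3B at -0.29 (SE 0.32). The medians were -0.03 for basal and mesenchymal genes, 0.04 for blood cell genes, 0 for the genes often hypermethylated in breast cancer, 0.03 for HOX genes, -0.01 for imprinted genes, 0 for housekeeping genes and 0.04 for the amplified genes. In this comparison the table and the treatment were the same split, and the placement of the libraries was uncertain.

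At finer scale a few regions had more tags in columns 3 and 4. Of 570264 sites tested, 81 passed, all higher (edgeR, adjusted p under 0.05), and 52 of them lay in the bins of at least 3 times the median tags, which held 3.82% of the tested sites. Among passing sites with a gene entry, the highest change was in an intron of APBB2 at position 40864177 of chromosome 4. This site had 0 and 1 tags in columns 1 and 2 and 49 and 13 in columns 3 and 4 (log2 5.64, SE 0.81, edgeR adjusted p = 2.34e-05). Intronic sites of PPM1E and INTS2 on chromosome 17, EYA2, BMP7, ZMYND8 and SULF2 on chromosome 20, and WDR4 and RUNX1 on chromosome 21 followed, with log2 changes of 3.63 to 4.64. DESeq2 called 1 site, and 394 passed with column position as a block. Leaving out columns 1 to 4 in turn gave 14 (13 of them lower), 146, 41 and 147. Of 381481 tiles of 1 kb, 2 passed, the APBB2 tile (log2 5.59, SE 0.83, adjusted p = 0.0249) and a tile with no gene entry on chromosome 20 from 53711000 (log2 4.48, SE 0.68, adjusted p = 0.0249). DESeq2 and total-tag scaling called 0 tiles, 83 passed with column position as a block, and leaving out columns 1 to 4 in turn gave 0, 47, 10 and 70. The tiles with a gene entry that came next by p did not pass: they were in BCAS1 (2.49, adjusted p = 0.0589), TBX2 (3.39, adjusted p = 0.0589), PTPN1 (2.52, adjusted p = 0.127) and PPL (3.16, adjusted p = 0.135).

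The share of listed sites with at least 1 tag, after thinning each column to 8803938 tags, was 66.15% and 69.96% in columns 1 and 2 and 69.72% and 72.47% in columns 3 and 4. The means were 68.06% ± 2.69 and 71.09% ± 1.94 (SD, n = 2 each), and the difference of 3.04 points did not pass (exact permutation test, two-sided p = 0.667). With at least 10 tags the means were 8.25% ± 0.54 and 8.24% ± 0.27 (SD, n = 2 each). Tag totals depend on sequencing and do not measure the amount of 5hmC in the genome.

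The title names the conversion of 5mC to 5hmC, so the changes of both measures were set side by side over 165178 tiles of 1 kb, although bisulfite reads cannot tell 5mC from 5hmC. The 2 changes had almost no correlation across tiles (Spearman rho -0.018, Pearson r -0.017), which are not independent replicates. Among tiles at or above the median of both tags and coverage, rho was -0.04. Sampling of reads and tags weakens such a correlation, so it does not show that the 2 changes are unrelated. Over tiles of any depth, leaving out column 1 or column 4 turned the sign of rho, to 0.007 and 0.003. The 5hmC side carries the uncertain placement of its libraries.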

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

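Column position as a block, both strands of a site summed, total-tag scaling of the gene lists, the upper coverage limit on the weighted level, leaving out libraries for level values, and all settings of the contrast of second against first columns were chosen after seeing the data. Where a library is left out, the lone library of its group is assumed to vary like the other group. Over single cytosines, the replicate 1 deviations of the 2 bisulfite groups had a correlation of 0.011. With a chi-square per cytosine of 1.153 to 1.212 between libraries, these deviations were mostly read sampling. The correlation therefore cannot tell whether the replicate numbers pair the libraries. With the replicate number as a block 17 tiles passed in place of 0, and 0 promoters passed. For 5hmC no analysis paired by replicate was possible because the columns carry no replicate number. A coverage minimum of 5 and the motif tiles were not run.

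The count of 0 tiles for 5mC held with limma, other tile sizes and a coverage minimum of 20, rose to 691 without overdispersion, and was 0 to 1 when a library was left out (1 without siTET2 replicate 1). Called cytosines went from 15 to 5 at a coverage minimum of 20, 54 without overdispersion and 0 with an F reference, and from 11 to 65 when a library was left out (65 without siTET2 replicate 1). The global difference of -0.13 points turned to 0.82 when weighted by reads, 0.85 weighted at 20 reads, 0.46 weighted over all listed cytosines and 0.75 weighted under the upper coverage limit. The share of sites with at least 10 tags turned from -0.01 to 1.11 points without thinning. The cause was not tested.

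By the descriptions, called 5hmC genes went from 0 to 1 with column position as a block and ranged from 0 to 20 with a column left out (20 without column 1). Called tiles went from 2 to 0 with total tags, 0 with DESeq2, 0 at 5 kb, 20 at 500 bp, 99 without a filter and 83 with column position as a block, and ranged from 0 (without column 1) to 70 (without column 4). Called sites went from 81 to 50 with total tags, 394 with column position as a block and 1 with DESeq2, and ranged from 14 (without column 1) to 147 (without column 4). The cell cycle call was lost with total tags (0 lists), and the lists called ranged from 0 (without column 1 or 4) to 1. The cause was not tested. By the descriptions, the Spearman correlation of both changes stayed between -0.04 and 0.007 in the settings run.

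No named promoter or gene below passed in the comparison it belongs to, and each turned its sign in at least 1 setting. At a coverage minimum of 20 the promoter difference was 0.05 points for XBP1, -0.12 for NEIL1, -1.8 for SPI1, -1.86 for CD8A, -0.53 for TOP2A, -1.27 for HMBS, -0.69 for GAPDH and -0.25 for ELF3. With a library left out it ranged from -0.01 to 0.33 for ESR1, -1.28 to 2.77 for GREB1, -0.53 to 0.28 for XBP1, -0.69 to 4.16 for DNMT3B, -1.67 to 4.12 for EGFR, -0.35 to 2.06 for SPI1, -2.15 to 2.02 for CD8A, -4.94 to 0.13 for ITGAM, -5.32 to 0.31 for CD14, -0.4 to 1.68 for TOP2A, -6.71 to 0.5 for MCM5, -1.37 to 7.81 for RUNX3, -0.22 to 1.28 for GAPDH and -7.42 to 0.82 for SGCE. With total tags the log2 change by the descriptions was 0.02 for GREB1 and 0.01 for PGR. With a column left out it ranged from -0.32 to 0.12 for TFF1, -0.27 to 0.29 for GREB1, -0.16 to 0.06 for PGR, -0.22 to 0.05 for GATA3, -0.09 to 0.24 for FOXA1, -0.32 to 0.02 for CXXC5, -0.67 to 0.17 for HOXB1, -0.02 to 0.6 for APPBP2, -0.06 to 0.29 for VMP1, -0.13 to 0.02 for BCAS4, -0.19 to 0.04 for BCAS3, -0.49 to 0.03 for TP63, -1.02 to 0.27 for SOX10, -0.43 to 0.04 for RPLP0, -0.12 to 0.65 for PEG10 and -0.54 to 0.1 for H19. Between second and first columns the log2 change was -0.08 for PGR after thinning, and with a column left out it ranged from -0.24 to 1.07 for SOX10, -0.82 to 0.67 for CD3E, -0.01 to 1.01 for CCNA2, -0.43 to 0.18 for CCNB1 and -0.18 to 0.03 for YWHAZ. Over all settings, the values of the named cytosines stayed called 28 times and lost the call with the same sign 36 times, those of the named 5hmC sites 60 and 21 times.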

Other observations

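All tests in this part were chosen after the data were seen, except the calls of 5hmC sites by the descriptions, with all columns or without one, which were planned, and 3 tests whose outcome was written down first: the tags outside CpG islands and promoters, the CpG-dense tiles without siTET2 replicate 1, and the other splits of those tiles. The first and second count columns of the 5hmC tables differed in many genes. Which treatment each column holds is not settled by the files, so none of these differences is assigned to TET2. Of 22520 genes, 4341 passed (edgeR with the table as a block), 1818 higher and 2523 lower in the second columns. With total-tag scaling 4778 passed and the split turned, 3176 higher and 1602 lower, and the median of all genes moved from a log2 of 0.03 to 0.1. DESeq2 without the block called 1268 and gave no adjusted p for 10042 genes, and edgeR without the block called 3943. With the block dropped as well as a column, 60 passed without column 1, 3441 without column 2, 2935 without column 3 and 2198 without column 4. The count of single sites depended on the setting, with 5840 called, 10301 with total-tag scaling, 7560 without a filter and 5979 after thinning. It was 0 under RLE scaling, without the block, or with both strands of a site summed. Of 39 oestrogen receptor targets 20 passed, 16 lower and 4 higher in the second columns (22 adjusted over the list alone; camera adjusted p = 0.0128, but adjusted p = 0.786 with an estimated correlation and 0.262 with fry). Among them CTSD, a lysosomal protease gene, had a log2 change of -0.59 (SE 0.07), GREB1 -0.43 (SE 0.06) and TFF1 -0.38 (SE 0.09), while the growth regulator gene MYC had 0.65 (SE 0.13) and XBP1 0.58 (SE 0.16).

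Of 20 luminal identity genes 6 passed, 5 lower and 1 higher in the second columns (8 adjusted over the list alone), and their camera call (adjusted p = 0.043) was lost with an estimated correlation (adjusted p = 0.786), with total-tag scaling and without the block, and fry gave an adjusted p of 0.19. Among them were SPDEF at -0.69 (SE 0.06), MLPH at -0.44 (SE 0.05), ESR1 at -0.27 (SE 0.06) and ZNF703 at 0.50 (SE 0.16). Of 39 HOX genes, which pattern the body axis, 10 passed, 8 higher and 2 lower (10 adjusted over the list alone; 28 lay above and 11 below 0), and their camera call (adjusted p = 0.0199) was lost with an estimated correlation (adjusted p = 0.786); fry gave 0.0896. Among them were HOXA9 at 0.95 (SE 0.15) and HOXB1 at -0.68 (SE 0.12). Of the cell cycle genes 1 of 22 passed, PCNA at 0.74 (SE 0.23), and 0 adjusted over the list alone. The camera call of that list (adjusted p = 0.043) was lost with an estimated correlation (adjusted p = 0.786), with total-tag scaling and without the block. With the block dropped as well as a column, the oestrogen receptor targets were called in each case and the HOX genes in all but the one without column 4; the luminal list was called only without column 2, and the cell cycle list without column 2 or 3. The list members named here kept their sign with RLE and total-tag scaling. The counts that passed in the other lists, over all genes and adjusted over the list alone, were 5 and 5 of 21 basal and mesenchymal genes and 2 and 2 of 11 blood cell genes. They were 9 and 12 of 28 genes often hypermethylated in breast cancer, 6 and 6 of 21 imprinted genes, 2 and 1 of 13 housekeeping genes and 6 and 9 of 14 amplified genes. For the 25 machinery genes they were 6 (1 higher and 5 lower) and 7, with 11 members above and 14 below 0. The machinery list was the only 1 that passed with fry (adjusted p = 0.0265, direction not recorded), but camera gave an adjusted p of 0.336. The TET2 gene had -0.24 (SE 0.10, adjusted p = 0.106). The highest changes were in genes with few sites, led by DTWD1 at 2.04 (SE 0.57, 3 sites) and LINC00904 at -1.66 (SE 0.52, 3 sites). Over tiles, the change between columns and the change in 5mC had a Spearman rho of -0.033.

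The unequal number of tags by itself is argued against as the source of the difference between columns. With the deeper column of each table thinned to the other, 71.8% of the called genes (3116 of 4341) were called again in the same direction. Thinning keeps each gene's share of tags, so it cannot remove other traits that go with a deeper library. The first column was the deeper in each table, so such traits and column position cannot be told apart. From tags outside CpG islands and promoters alone, 42.8% (1857 of 4341) were called again and 0 in the opposite direction, out of 2216 called there. Of the 4341, 640 had too few such tags to be tested; of the 3701 tested, 50.2% were called again and 3611 had the same sign, with a median absolute log2 change of 0.33 against 0.37 from all tags. The larger island and promoter share of the second columns is therefore not the whole cause for those 1857 genes and stays open for the rest. A smaller contrast between 5hmC-rich and 5hmC-poor genes in the second columns is a candidate explanation, since the change fell with the tags per site (Spearman rho -0.476 over genes), but the comparison by the descriptions had -0.367 as well. A mislabelled sample, meaning libraries tied to the wrong table, stays open and undecided: the first principal component of the tiles, 47.3% of the variance, parted columns 1 and 3 from columns 2 and 4, but that restates the difference between columns and is also the split by depth. An effect of TET2 knockdown stays open and untested, because no source names the columns. If the columns followed the library numbers, the second columns would hold the siTET2 libraries, but the sample descriptions place them otherwise.

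In tiles with 30 or more cytosines and 20 to 80% methylation, gains in siTET2 outnumbered losses, 259 to 111 of 2650 tiles at an unadjusted p under 0.05 (70.0% gains); this class was picked after 21 classes had been looked at, and 0 tiles passed adjustment. The pattern may come from siTET2 replicate 1, since gains were 46.8% without it. The mean levels of the class were 39.12% and 39.1% with siNT and 40.08% and 38.93% with siTET2 replicates 1 and 2. The other splits of the 4 libraries gave at most 67.0% in one direction, below the real 70.0%, but 3 splits are too few for a share under 0.05. The bound written beforehand, that no other split reaches the real share, was therefore wrong for this design.

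The 81 sites called by the descriptions lay mostly in the bins of at least 3 times the median tags (52 sites, 64.2%). A higher tag count per site there is argued against, since the share was 18.7 times that of tested sites matched on tags. A gain in copy number in the libraries of the second table is argued against too, since their share of tags in these bins was 0.993 times that of the first table. Among sites called higher without column 3, the share in these bins was 6.31 times that of matched sites, against 18.7 with all columns. Some of the pattern thus remained without column 3, but that column is not excluded as its main source. This ratio was tried after another measure did not decide. By that measure, the scaled counts of column 3 at the 81 sites were 1.92 times those of column 4 in the median. Without column 1 a single site was called higher, so the calls depended on that column too. A difference between the tables, which is also the treatment by the descriptions, stays open and untested.

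Mitochondrial cytosines read as methylated at 21.37% and 21.38% in the siNT libraries and 21.7% and 20.56% in the siTET2 libraries, over 191 to 202 listed cytosines.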
